A study of Mus musculus with 9 samples.

How the data were processed

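The bead-array signals were deposited by the authors as intensities without normalization, per the file headers and the values. A detection p-value for each probe and array was deposited beside the intensity, per the file headers. A second deposited table held log2 values that were quantile normalized between arrays; it tracked the intensities after an RMA-type background correction and quantile normalization (Pearson r of 0.99998). Biotin-labelled RNA in 1 colour was read on each array, per the labels. BeadStudio 3.2, RMA and lumi were named in the submitters' processing notes, without role or order.

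Intensities were corrected for background by normexp using the detection p-values, with an offset of 16, then quantile normalized and taken to log2. Of 25697 probes, 23978 carried 1 gene symbol and 1719 carried none. Symbols were brought to current ones by Entrez identifier. Probes with a detection p under 0.01 on at least 1 array were kept (13032, of which 12292 were named), and each gene was read from its brightest probe, giving 8938 genes. A gene was below background in a group when no array of the group detected any of its probes. Lists were counted on these genes.

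Groups were compared by limma over all 9 arrays, with 4 residual and 5.26 prior degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method within each of 10 comparisons. The test was two-sided. The lone fibroblast array was assumed to vary like the other groups. Of 23 gene lists, 20 with at least 5 measured genes were tested by camera with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists of a comparison. Signature genes were those called and at least 4-fold apart between control NSC and fibroblast. The position of an array was the median over these genes of its distance from fibroblast, as a percent of the distance between fibroblast and control NSC.

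The groups, tests, gene lists, other settings and the rule for naming genes were chosen before the data were examined, except a fit to arrays of the same number format and the tests of explanations in the closing section, with a second p53 list and shuffled Hox profiles, which were added later. By that rule the text names the 8 largest rises and 8 largest falls in control NSC against fibroblast, each iNSC group against control NSC, and late against early 4F cells, and the 3 largest each way elsewhere. Candidates had an adjusted p under 0.05, arrays of the groups that did not overlap, detection on every array of the brighter group and a symbol that was not a predicted name. The introduced factors were named whatever their test, as were up to 4 members of each described list, the 2 largest called rises and 2 largest called falls.

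The alternatives were RMA-type background correction, no background correction, an offset of 50, median scaling, the submitters' processed values, no detection filter, detection on at least 2 arrays, the mean of a gene's probes, a variance trend with robust fitting, replicate number as a block, only the 2 groups compared, and leaving out each array of a group of 2. A fit to arrays of the same number format was added after the data were seen. Array slide as a block was not run, since no slide was given. Under median scaling the median over all genes was 0.26 log2 for control NSC, 0.27 for late 4F and 0.20 for 5F cells against fibroblast, and -0.18 for early 4F against control NSC. It was 0.18 for late and 0.12 for 5F against early 4F cells.

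The procedure was tested on simulated data of 8938 genes. In simulated control NSC against fibroblast it recovered 11.1% of genes changed 1.5-fold, 82.7% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls among 141. In simulated late 4F cells against control NSC it recovered 33.3%, 83.6% and 100%, with 15 false calls among 161. In a single simulated run the Hox list, raised by 1 log2 unit in late 4F cells, was called and 0 of the others were. Noise was drawn independently for each gene, so this cannot show how the list test acts on correlated genes. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.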

Results

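Gene expression was measured in cultured mouse cells on 9 single-colour bead arrays, with 1 array per sample and 5 groups. The fibroblast group held 1 array from embryonic fibroblasts of the CF1 outbred stock. Control neural stem cells (NSC), brain-type stem cells grown from OG2-Rosa mice, held 2 arrays. The other 6 arrays came from induced neural stem cells (iNSC), which are fibroblasts turned into neural stem-like cells by added transcription factors. These were 2 arrays of 4-factor (4F) cells at early passage, 2 of 4F cells at late passage and 2 of 5-factor (5F) cells, whose passage was not given in the sources used here. All replicates were biological according to the series description. Between 10105 and 10534 of 25697 probes were detected per array (39.3% to 41.0%), and array median signals ran from 113 to 125. After filtering, 8938 named genes were compared. The lone fibroblast array gave no replicate error, so every test against it borrowed the spread of the other groups. The number of arrays limited the precision throughout.

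The deposited signals came in 2 number formats. The fibroblast array and both early 4F arrays carried several decimals, and the other 6 arrays carried 1. Of the 10 comparisons between groups, 4 set arrays of the same format against each other: early 4F iNSC with fibroblast, late 4F iNSC with control NSC, 5F iNSC with control NSC, and 5F with late 4F iNSC. In the other 6, number format and group could not be told apart.

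Neural stem cells and fibroblasts were compared first, to find the genes that separate these cell types. The fibroblast array, the only one with Xist above background, need not match the cells the iNSC came from. Mouse stock and sex may thus add to every difference from it, which was not tested. The mouse stock behind the iNSC is not stated here, so stock may also add to their differences from control NSC, likewise untested. Olig1, a transcription factor of the oligodendrocyte lineage, had a log2 signal of 14.61 ± 0.13 (SD, n = 2) in control NSC and 4.66 in fibroblast, at least 497-fold apart. Slc1a3, the glial glutamate transporter, was higher by at least 175-fold, and Fabp7, a fatty acid binding protein of radial glia, by at least 53.3-fold. Acta2, the smooth muscle actin, was lower by at least 579-fold and Lox, an enzyme that cross-links collagen, by at least 358-fold. In all, 5296 genes passed an adjusted p of 0.05 in limma, 2871 higher and 2425 lower in control NSC, and 3499 of these differed at least 2-fold. The other genes of largest rise were Aldoc, a glycolytic enzyme of astrocytes (at least 203-fold), Bcas1, a protein of early oligodendrocytes (at least 149-fold), the proteoglycan Bcan (at least 64.9-fold), Vxn, a neurogenesis regulator (at least 50.5-fold), and Tril, a glial toll-like receptor partner (at least 61.6-fold). The other largest falls were Timp1, a protease inhibitor (at least 506-fold), the matrix protein Ccn2 (at least 481-fold), the proteoglycan Bgn (at least 548-fold), the growth factor Igf2 (at least 483-fold), the membrane-binding protein Anxa3 (at least 408-fold) and the collagen Col1a1 (at least 243-fold). A fold is given as "at least" wherever the dimmer group was below background or was detected on 1 of its 2 arrays. It compares the mean of the brighter group with the mean, in the dimmer group, of whichever was higher on each array: the lowest signal of any detected probe or the probe's own signal. Genes were ranked by the fitted difference, which for such genes is not a bound.

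Of 20 tested gene lists 11 passed between these cell types, 3 of them with an estimated correlation too. All 31 measured fibroblast and mesenchyme genes fell, with a median of -4.85 log2, or -3.78 with genes below background set at their bound (adjusted p = 1.03e-18, camera). Of 12 smooth muscle genes 11 fell (median -4.31, or -3.78 with bounds, adjusted p = 8.82e-08), among them Acta2 and the tropomyosin Tpm2 (at least 150-fold). All 15 cholesterol synthesis genes rose (median 2.31, adjusted p = 4.76e-07), such as Idi1, an isoprenoid isomerase (at least 9.37-fold), and Insig1, a regulator of sterol synthesis (3.68). These counts were the same when adjusted over the list alone. With an estimated correlation the fibroblast and smooth muscle lists held in all 4 comparisons with fibroblast, the cholesterol list held in this comparison only, and no other list call held.

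Several further lists passed with the preset correlation only. Of 24 neural stem cell and radial glia genes 17 rose and 3 fell, with a median of 2.37, or 2.03 with bounds (adjusted p = 6.24e-05). Slc1a3 and Bcan rose most, while the matrix protein Tnc (-2.34) and the Notch target Hes1 (-1.23) fell; adjusted p = 0.215 with an estimated correlation. Of 25 cell cycle genes 21 rose and 1 fell (median 2.59, or 2.38 with bounds, adjusted p = 1.62e-07), among them the replication clamp Pcna (3.65); adjusted p = 0.0634 with an estimated correlation. Of 23 interferon response genes 21 fell and 1 rose (median -3.25, or -2.46 with bounds, adjusted p = 1.32e-09), led by Usp18, which removes the ubiquitin-like tag Isg15 (at least 75.05-fold); adjusted p = 0.0533 with an estimated correlation. All 15 TGF-beta and BMP targets fell, Inhba, an activin subunit, by at least 180-fold (adjusted p = 1.32e-09); adjusted p = 0.0634 with an estimated correlation. Of 23 Hox genes, which set position along the body axis, 15 fell and 1 rose (median -1.24, or -0.48 with bounds, adjusted p = 6.24e-05); adjusted p = 0.0810 with an estimated correlation. Of 17 p53 response and growth arrest genes 13 fell and 3 rose (median -1.36, adjusted p = 0.00240); adjusted p = 0.267 with an estimated correlation. Of 12 antigen presentation genes 10 fell and 1 rose (adjusted p = 0.00240); adjusted p = 0.0786 with an estimated correlation. All 5 measured microglia and blood genes fell (adjusted p = 0.00104); adjusted p = 0.0830 with an estimated correlation. Every count in this group of lists was the same when adjusted over the list alone.

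Each iNSC group was then compared with fibroblast, to see how far it differed from that cell type. Olig1 rose in all 3 groups, by at least 462-fold in early 4F, 506-fold in late 4F and 491-fold in 5F cells. Slc1a3 rose by at least 204-fold in early 4F cells and Nup210, a nuclear pore protein of neural progenitors, by at least 107-fold. Aldoc rose by at least 182-fold in late 4F cells, where Bcas1 rose by at least 126-fold. In 5F cells Aldoc rose by at least 229-fold and Mt3, a metallothionein of the nervous system, by at least 152-fold. Bgn fell by at least 544-fold in early 4F, 506-fold in late 4F and 522-fold in 5F cells. Lox fell by at least 355-fold in early 4F cells and 341-fold in 5F cells, and Col1a1 by at least 241-fold in early 4F cells. Acta2 fell by at least 535-fold and Ccn2 by at least 444-fold in late 4F cells, and Anxa3 by at least 389-fold in 5F cells. Early 4F cells differed from fibroblast at 5285 genes (2897 higher, 2388 lower), late 4F cells at 5492 (3005 and 2487) and 5F cells at 5368 (2935 and 2433). Between arrays of the same format only, early 4F and fibroblast differed at 4336 genes (2346 higher, 1990 lower).

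Fibroblast genes fell and neural genes rose in every iNSC group against fibroblast. All 31 fibroblast and mesenchyme genes fell in early 4F (median -4.39, or -4.04 with bounds, adjusted p = 8.40e-19) and late 4F cells (median -4.49, or -3.67 with bounds, adjusted p = 6.64e-18). In 5F cells 30 fell (31 adjusted over the list alone; median -4.74, or -4.17 with bounds, adjusted p = 5.91e-18). All 12 smooth muscle genes fell in each group (medians -3.97, -4.38 and -3.77, or -3.64, -3.70 and -3.45 with bounds). Of 24 neural stem cell genes 17 rose and 4 fell in early 4F cells, such as Bcan (at least 65.4-fold) and the transcription factor Zic1, which fell by at least 4.99-fold. In late 4F cells 18 rose and 4 fell, and in 5F cells 16 rose (17 adjusted over the list alone) and 4 fell. The list passed in all 3 groups with preset correlation (adjusted p = 7.25e-05, 9.32e-05 and 3.56e-05); adjusted p = 0.235, adjusted p = 0.218 and adjusted p = 0.215 with an estimated correlation. Cell cycle genes rose, 21 of 25 in early 4F and 22 in both other groups, such as Plk1, a mitotic kinase (4.19 in early 4F cells); adjusted p = 0.0724, adjusted p = 0.0597 and adjusted p = 0.0605 with an estimated correlation. The interferon list fell too, with 21, 21 and 22 of 23 genes lower; adjusted p = 0.0646, adjusted p = 0.0597 and adjusted p = 0.0605 with an estimated correlation. Of 15 cholesterol synthesis genes 14, 13 and 14 rose, and Msmo1, a sterol demethylase, fell in each group (-1.30, -1.19 and -1.24 log2); adjusted p = 0.0708, adjusted p = 0.0597 and adjusted p = 0.0605 with an estimated correlation. The TGF-beta and BMP targets fell, 12, 14 and 14 of 15; adjusted p = 0.0797, adjusted p = 0.0597 and adjusted p = 0.0605 with an estimated correlation. Antigen presentation genes fell, 8, 10 and 10 of 12; adjusted p = 0.0797, adjusted p = 0.0597 and adjusted p = 0.0605 with an estimated correlation. All 5 microglia and blood genes fell in each group; adjusted p = 0.0913, adjusted p = 0.0985 and adjusted p = 0.0956 with an estimated correlation. Of 17 p53 genes 11, 14 and 12 fell and 4, 3 and 2 rose, while the secreted binding protein Igfbp3 rose in each (5.46, 4.44 and 4.50); adjusted p = 0.420, adjusted p = 0.196 and adjusted p = 0.342 with an estimated correlation. In each of these comparisons 10 of 20 lists passed with preset correlation, and 2 held with an estimated correlation.

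The genes separating fibroblast from control NSC were used to place each iNSC group between these cell types. Over 780 genes at least 4-fold higher in fibroblast, early 4F cells lay at a median of 95.9% ± 0.17 (SD, n = 2) of the log2 distance. Late 4F cells lay at 100.6% ± 0.22 and 5F cells at 99.8% ± 0.08. Over 685 genes at least 4-fold higher in control NSC, the values were 88.2% ± 0.22, 93.1% ± 0.09 and 96.3% ± 0.30. The control NSC arrays, each placed against the other, had 100% ± 1.11 and 100% ± 0.53. No test was made of these values, since with 2 arrays against 2 an exact test cannot give a p under 0.333. Genes detected on the fibroblast array alone count here, and lie near 100% wherever the neural groups are at background. Over probes detected on at least 2 arrays the first values were 79.6% for early 4F, 99.4% for late 4F and 95.3% for 5F cells. With median scaling the second value for early 4F cells was 77.9%. Early 4F arrays share the number format of fibroblast and not of control NSC, so their lower position cannot be told apart from format.

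**Figure D1:**
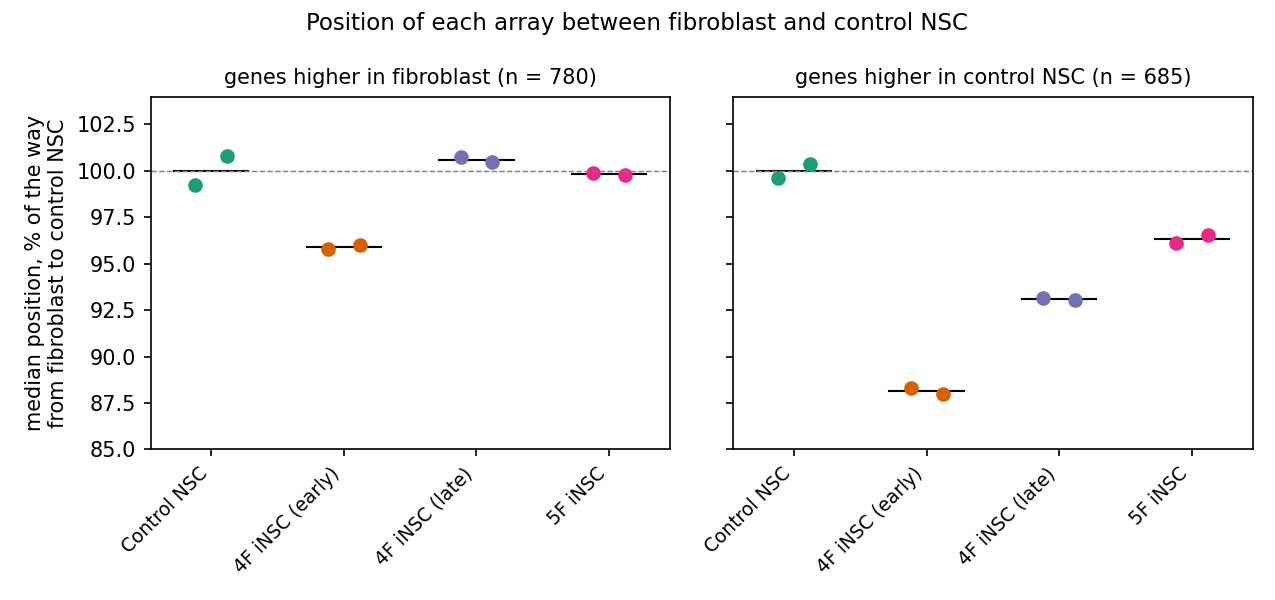
Percent of the log2 distance from fibroblast (0) to control NSC (100) for each array, as the median over 780 genes higher in fibroblast (left) and 685 genes higher in control NSC (right). Points are arrays by group and lines are means. Early 4F cells sit lowest in both panels, at 95.9% and 88.2%, and their arrays share the number format of fibroblast, not of control NSC.

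Signature genes that still differed from control NSC were counted in each iNSC group. Of the 780 fibroblast-high genes, 262 (33.6%) were still higher than in control NSC in early 4F cells, 116 (14.9%) in late 4F cells and 128 (16.4%) in 5F cells. Among independent genes 175, 103 and 66.0 would be so. Of the 685 NSC-high genes, 312 (45.5%), 239 (34.9%) and 173 (25.3%) were still lower, against 145, 99.9 and 68.6. Unchanged groups simulated around the mean of the observed control arrays gave 0 such genes. Their difference from control NSC holds no control array error, nor the real effects. The 0 therefore cannot show how much the shared control arrays add, and part of each excess may come from them. Some fibroblast-high genes had gone past control NSC, with 67, 101 and 80 lower than in it. Likewise 122, 88 and 76 NSC-high genes were higher than in control NSC.

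The correlation across genes between pairs of arrays followed the groups. Replicates had Pearson r of 0.994 in control NSC, 0.987 in early 4F, 0.993 in late 4F and 0.993 in 5F cells. Control NSC arrays correlated with 5F arrays at 0.954 to 0.955, with late 4F arrays at 0.947 to 0.948 and with early 4F arrays at 0.920 to 0.934. Late 4F and 5F arrays correlated at 0.970 to 0.972. The fibroblast array correlated with the early 4F arrays, which share its number format, at 0.739 to 0.749. With control NSC arrays its r was 0.729 to 0.731, with late 4F arrays 0.723 and with 5F arrays 0.724 to 0.725. These are across genes, which are not independent replicates, and no test was made.

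The introduced factors were read in every group, to see whether their signals set the iNSC lines apart. From knowledge of the study, the 4 factors are taken to be Pou3f4, Sox2, Klf4 and Myc, and the added factor of 5F cells Tcf3, which had no named detected probe and was not analysed here. Pou3f4 (Brn4, Entrez gene 18994, chromosome X), a neural POU-domain factor, reached 9.19 ± 0.09 log2 (SD, n = 2) in early 4F cells and was below background in every other group. It was at least 12.9-fold higher than in control NSC (adjusted p = 1.70e-07), and lower in late 4F cells by at least 11.9-fold and in 5F cells by at least 12.3-fold than in early 4F cells. Sox2 (Entrez gene 20674, chromosome 3), which maintains neural stem cells, had 9.68 ± 0.10 in control NSC, 8.49 ± 0.33 in early 4F, 9.94 ± 0.07 in late 4F and 10.11 ± 0.04 in 5F cells on its brighter probe, and 4.34 in fibroblast. On that probe early 4F cells were below control NSC by -1.20 ± 0.17 (SE; adjusted p = 5.23e-04). A second Sox2 probe gave the reverse, with 10.57 ± 0.15 in early 4F cells and 8.003 ± 0.37 in control NSC (2.56 higher, adjusted p = 1.23e-05 over probes). The mean of both Sox2 probes put early 4F cells 0.68 above control NSC and above late 4F and 5F cells (-0.27 and -0.30 in these against early 4F). Only the first of these differences passed (adjusted p = 0.00906, 0.230 and 0.193), and the direction depended on the probe. Whether the Pou3f4 probe or either Sox2 probe reads the introduced copy was not given in the sources used here. Klf4, a factor of epithelial cells, was 10.08 in fibroblast and 6.22 in control NSC. Between iNSC groups it differed on its brightest probe only as 0.60 ± 0.19 (SE) higher in 5F than in early 4F cells (adjusted p = 0.0319). That comparison crossed the number formats. The dimmer Klf4 probes, at 4.53 to 5.10 in these groups, gave -0.29 and 0.16 and did not pass (limma, adjusted p = 0.283 and 0.415 over probes). Myc, a driver of growth, ranged from 6.28 to 6.82 and did not pass in any comparison.

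**Figure D2:**
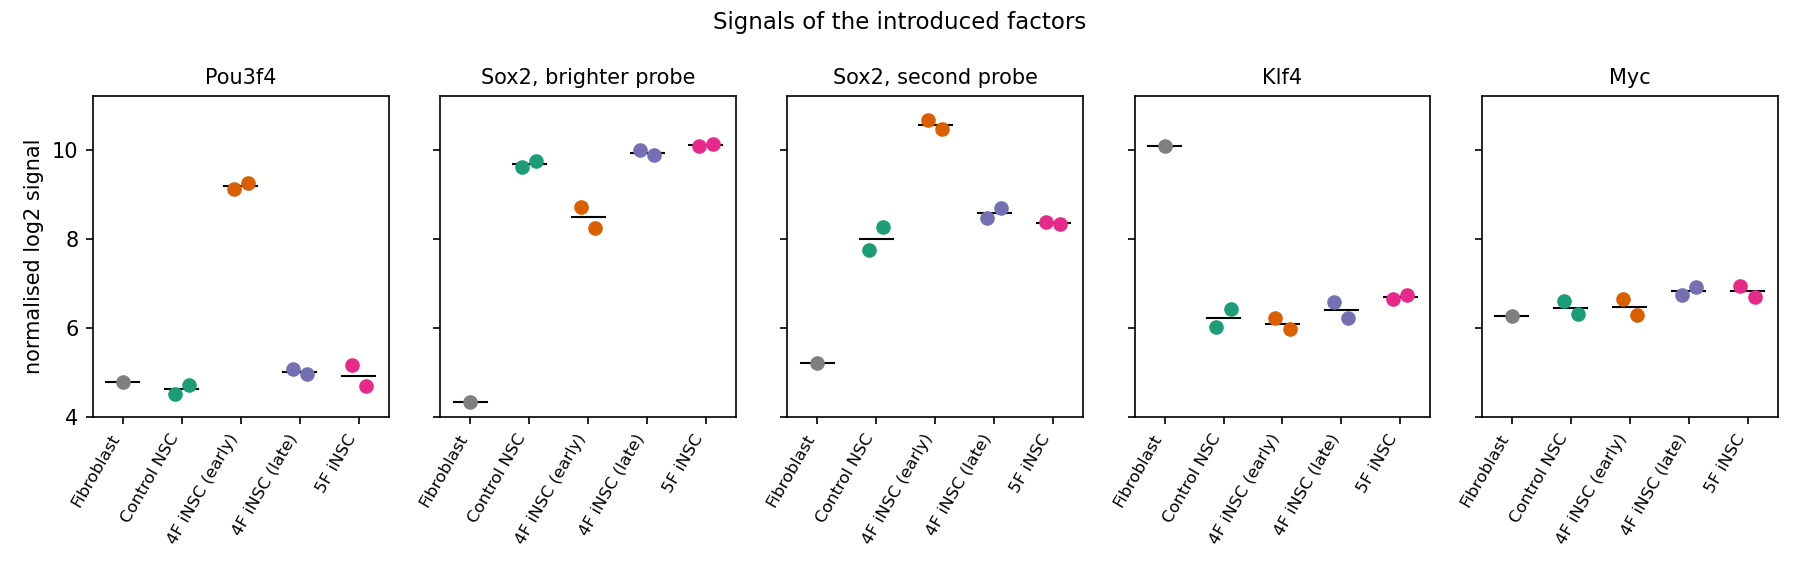
Normalised log2 signal of the introduced factors on each array by group, with lines at group means. Panels show the brightest probe of each measured factor and the second Sox2 probe, and the dimmer Klf4 probes are not drawn. Pou3f4 is above background only in early 4F cells (9.19), where the brighter Sox2 probe is lowest among the neural groups (8.49) and the second Sox2 probe highest (10.57).

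Early 4F iNSC were compared with control NSC, to see which genes still set the induced cells apart at early passage. Hoxc6, a homeobox gene of the trunk, had 10.84 ± 0.29 log2 (SD, n = 2) in early 4F cells and 4.54 ± 0.13 in control NSC, at least 40.4-fold apart. Nkx2-2, a ventral neural tube and oligodendrocyte factor, was lower by at least 46.1-fold, and the growth factor Angpt2 by at least 42.8-fold. The other genes of largest rise were Hoxc9 (at least 32.7-fold), Hoxb7 (at least 20.8-fold), Ccn2 (at least 18.3-fold), the glycoprotein hormone Stc2 (at least 33.5-fold), the sulfotransferase Hs3st1 (at least 22.0-fold), Hoxd8 (at least 16.01-fold) and Ttyh1, a chloride channel of neural stem cells (4.88 log2). The largest falls also took in the receptor partner Ramp1 (at least 64.0-fold), the lysosomal protease Ctsc (at least 30.0-fold), the X-linked lymphocyte-regulated gene Xlr4a (at least 28.1-fold), Pdrg1, a prefoldin-like protein (at least 20.9-fold), the RNA-binding protein Igf2bp3 (at least 22.5-fold) and Thumpd1, a tRNA acetylation factor (at least 20.1-fold). In all, 3891 genes differed, 2004 higher and 1887 lower, with 1372 at least 2-fold.

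Hox genes as a list were higher in early 4F cells than in control NSC, with 17 of 23 up, 1 down and 5 not passing (the same adjusted over the list alone). Their median was 2.31, or 1.64 with bounds (adjusted p = 1.95e-09; adjusted p = 0.0788 with an estimated correlation). Hoxa4 fell by at least 4.03-fold. Of 15 cholesterol synthesis genes 13 fell, as many adjusted over the list alone, with a median of -0.91 (adjusted p = 3.15e-05; adjusted p = 0.0788 with an estimated correlation). Msmo1 fell by 2.53 and Fdps, which makes farnesyl pyrophosphate, by 1.14. The neural stem cell list did not pass as a whole, with 9 genes up, 6 down and 9 not passing of 24, the same adjusted over the list alone. Sox21, a neural progenitor factor (2.45), and Tnc (1.44) rose, while Zic1 fell by at least 3.82-fold and Fabp7 by 2.03. Of 31 fibroblast genes 5 rose and 5 fell (4 adjusted over the list alone), among them Mmp14, a membrane protease (at least 4.80-fold), Pcolce, a collagen processing protein (at least 5.20-fold), and the fibulin Fbln2 (-1.35). The median of the fibroblast list was -0.02 (0 with bounds) and its mean 0.21, and the list did not pass (adjusted p = 1.00). This comparison crossed the 2 number formats, and of 624 genes with several called probes 53 (8.49%) had probes called in opposite directions. With median scaling 31.9% of called genes were higher, against 51.5%, and the mean of the neural stem cell list was -0.20, against 0.04.

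Late 4F iNSC were compared with control NSC to see which differences were present at late passage. Hoxb7 had 10.68 ± 0.03 log2 (SD, n = 2) in late 4F cells and 4.46 ± 0.17 in control NSC, at least 36.1-fold apart. Igfbp4, a binding protein for insulin-like growth factors, was lower by at least 169-fold and Ramp1 by at least 59.9-fold. The other genes of largest rise were Hoxc6 (at least 20.2-fold), Hoxd8 (at least 15.7-fold), Hoxb2 (at least 15.6-fold), Hoxc9 (at least 11.9-fold), Stc2 (at least 21.6-fold), the tetraspanin Cd82 (4.15 log2, SE 0.24) and the guidance ligand Efna5 (at least 8.05-fold). The other largest falls were Nkx2-2 (at least 42.9-fold), Angpt2 (at least 39.9-fold), Ctsc (at least 27.9-fold), the stress-response gene Ier3 (at least 25.3-fold), the lipase Lpl (at least 16.9-fold) and Thumpd1 (at least 18.7-fold). In all, 2483 genes differed, 1179 higher and 1304 lower, with 849 at least 2-fold. Arrays of the same format only gave 2880 genes (1400 higher, 1480 lower). Leaving out 1 array gave 1444 genes without control NSC replicate 1, 1495 without control NSC replicate 2, 1583 without late 4F replicate 1 and 1581 without late 4F replicate 2.

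Of 23 Hox genes 15 rose and 1 fell in late 4F cells, the same adjusted over the list alone, with a median of 2.17, or 1.30 with bounds (adjusted p = 2.79e-11; adjusted p = 0.0570 with an estimated correlation). Of 15 cholesterol synthesis genes 13 fell, also over the list alone (median -0.88, adjusted p = 7.81e-07; adjusted p = 0.0570 with an estimated correlation), such as Msmo1 (-2.41) and the sterol demethylase Cyp51 (-1.49). Of 17 p53 response and growth arrest genes 11 fell and 1 rose, the same adjusted over the list alone, with a median of -0.69 (adjusted p = 8.27e-05; adjusted p = 0.366 with an estimated correlation). Igfbp7, a secreted growth inhibitor, fell by at least 9.29-fold and the cell cycle inhibitor Cdkn1c by at least 3.29-fold, while the inhibitor Cdkn2b rose by 1.08. Of 24 neural stem cell genes 6 rose and 7 fell (8 and 8 adjusted over the list alone). Fgfr3, a growth factor receptor of glial progenitors (at least 3.44-fold), and Sox21 (0.87) rose, while the endothelin receptor Ednrb fell by 3.45 and Zic1 by at least 3.56-fold. The neural list's median was 0.09, its mean -0.16 and its test pointed down without passing. Of 31 fibroblast genes 3 rose and 5 fell, the same over the list alone, among them Twist1, a mesenchymal transcription factor (at least 7.29-fold up), and Sparc, a collagen-binding protein (-1.32). The fibroblast list had a median of 0.03 (0 with bounds) and a mean of 0.04, its test pointed down, and it did not pass (adjusted p = 0.961). Of 13 astrocyte genes 6 fell and 1 rose (2 adjusted over the list alone; adjusted p = 0.0557), with the gap junction gene Gja1 lower by -4.32 and the chaperone Clu by at least 9.52-fold.

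For 5F iNSC the comparison with control NSC asked what the cells made with a further factor still lacked or kept. Acta2 had 10.15 ± 0.25 log2 (SD, n = 2) in 5F cells and 4.52 ± 0.08 in control NSC, at least 25.02-fold apart. Hoxc9 was higher by at least 19.4-fold, Ramp1 lower by at least 61.9-fold and Angpt2 by at least 41.2-fold. The other genes of largest rise were Hoxc6 (at least 19.9-fold), Hoxd8 (at least 16.9-fold), Hoxb7 (at least 11.22-fold), the membrane mucin Pdpn (4.48 log2, SE 0.13), Hs3st1 (at least 13.7-fold) and Ttyh1 (4.26). The other largest falls were Xlr4a (at least 27.0-fold), the adhesion adaptor Efs (at least 23.7-fold), Ier3 (at least 26.2-fold), the secreted protein Dcpp1 (at least 24.1-fold), Lpl (at least 17.4-fold) and Thumpd1 (at least 19.3-fold). In all, 1651 genes differed, 756 higher and 895 lower, with 685 at least 2-fold. Arrays of the same format only gave 1934 genes (919 higher, 1015 lower). With median scaling 36.1% of called genes were higher, against 45.8%. Leaving out 1 array gave 970 genes without control NSC replicate 1, 1026 without control NSC replicate 2, 1068 without 5F replicate 1 and 1097 without 5F replicate 2.

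Of 23 Hox genes 13 rose and 1 fell in 5F cells (14 and 1 adjusted over the list alone), with a median of 1.40, or 0.43 with bounds (adjusted p = 6.88e-11; adjusted p = 0.0608 with an estimated correlation). Of 15 cholesterol synthesis genes 11 fell (12 adjusted over the list alone; median -0.80, adjusted p = 1.20e-07; adjusted p = 0.0608 with an estimated correlation), such as Msmo1 (-2.47) and Insig1 (-1.32). Of 24 neural stem cell genes 7 rose (8 adjusted over the list alone) and 3 fell. Fgfr3 (at least 3.26-fold) and Tnc (1.58) rose, while Zic1 fell by at least 3.67-fold and Nr2e1, a nuclear receptor of neural stem cells, by at least 2.42-fold. Of 31 fibroblast genes 4 rose and 4 fell, the same adjusted over the list alone, with Twist1 up by at least 9.32-fold and Fbln2 down by 2.36. Neither list passed as a whole (adjusted p = 0.281 and 0.698), and the fibroblast list had a median of -0.05 (0 with bounds), a mean of 0.01 and a test pointing down.

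Across the 3 iNSC groups, 12 of 23 Hox genes were called higher than in control NSC in every group: Hoxa2, Hoxa5, Hoxa7, Hoxb2, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxc6, Hoxc9, Hoxd4 and Hoxd8. All 3 groups shared the same 2 control NSC arrays. Against fibroblast, Hoxa7 was higher in early 4F cells by 3.49 and Hoxa2 in late 4F and 5F cells by 2.87 and 2.88. Hoxd10 was lower than in fibroblast in all 3, by at least 3.005-fold, 2.80-fold and 2.89-fold.

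**Figure D3:**
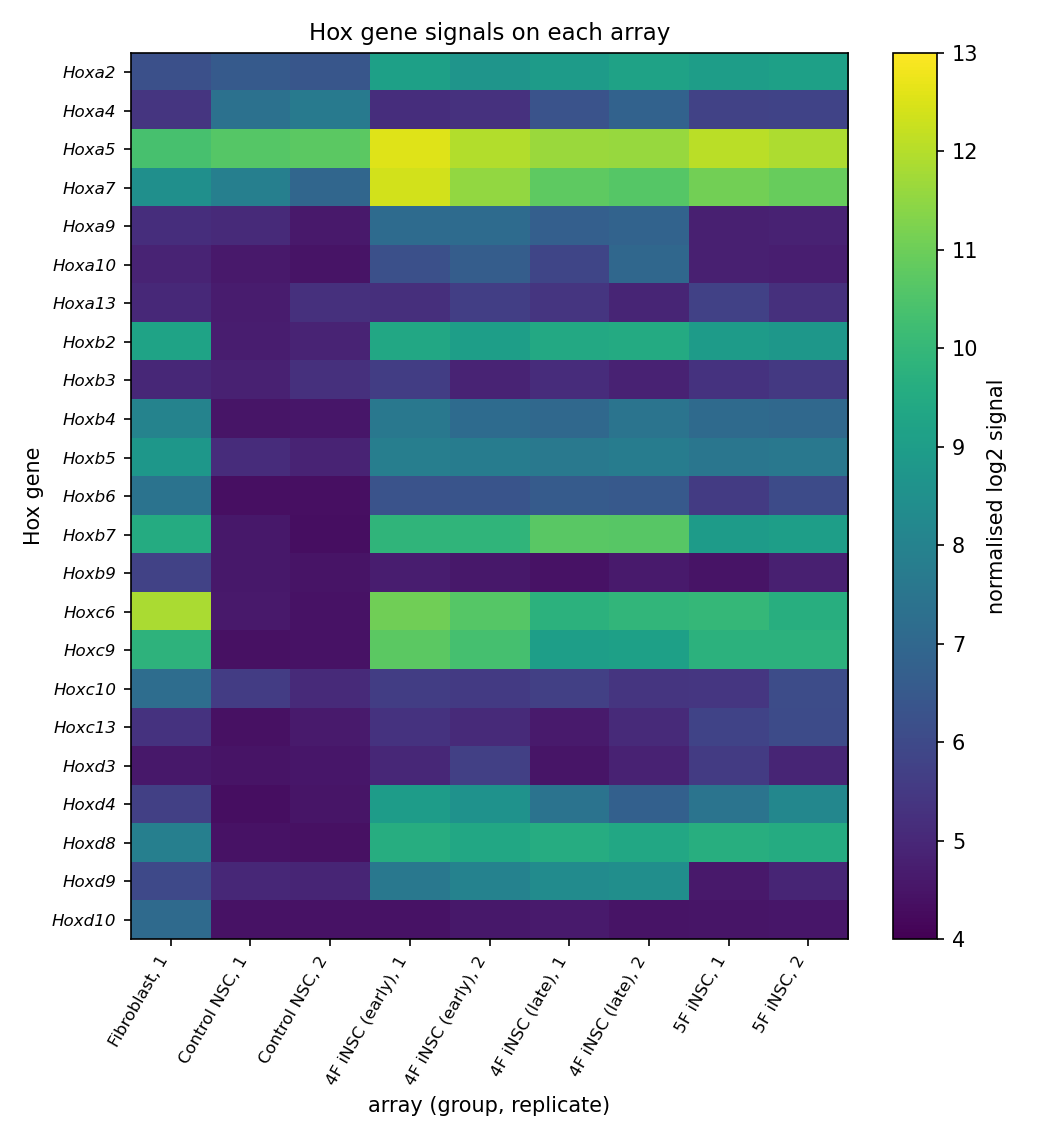
Normalised log2 signal of 23 Hox genes (vertical) on each of 9 arrays (horizontal, by group and replicate), with colour from 4 to 13. Hoxc6 reaches 10.84 in early 4F, 9.84 in late 4F and 9.82 in 5F cells against 4.54 in control NSC.

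Late and early passage 4F cells were compared to see what changed with passage. Ifitm3, an interferon-induced membrane protein, had 10.86 ± 0.28 log2 (SD, n = 2) in late cells and 6.44 ± 0.10 in early cells, a rise of 4.42 ± 0.18 (SE). Ddit4l, an inhibitor of mTOR signalling, fell by at least 34.4-fold, and Ccn2, among the genes raised at early passage, by at least 16.9-fold. The other largest rises were Anxa1, a phospholipid-binding protein (at least 12.3-fold), the monooxygenase Fmo1 (at least 13.2-fold), Cd82 (3.77 log2), the protocadherin Pcdh10 (at least 11.6-fold), the sensory neuron factor Pou4f1 (at least 5.88-fold), the matrix protein Sparcl1 (at least 3.52-fold) and the pentraxin Nptx1 (2.56). The other largest falls were the complement regulator Cd59a (at least 18.2-fold), the membrane skeleton protein Epb41l3 (at least 12.8-fold), Reln, which guides neuron migration (at least 12.6-fold), the mitochondrial kinase Ckmt1 (at least 13.7-fold), Tuft1 (at least 10.8-fold) and the protease inhibitor Timp3 (at least 12.4-fold). In all, 3885 genes differed, 1858 higher and 2027 lower in late cells, with 1259 at least 2-fold.

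Of 17 p53 response and growth arrest genes 13 fell and 1 rose from early to late passage, the same adjusted over the list alone, with a median of -1.14, or -1.08 with bounds (adjusted p = 5.85e-05; adjusted p = 0.865 with an estimated correlation). Bbc3, which triggers cell death, fell by 2.75 and Cdkn2b by 2.49, while Gadd45a, a DNA damage gene, rose by 0.75. It was the only list of 20 to pass. Of 25 cell cycle genes 12 rose and 4 fell, the same over the list alone, such as Pcna (1.65) and the cyclin gene Ccnd2 (-1.42). Of 24 neural stem cell genes 4 rose (5 adjusted over the list alone) and 6 fell, with Fabp7 up by 1.54 and Ednrb down by 3.26. Of 31 fibroblast genes 4 rose (2 adjusted over the list alone) and 4 fell, Mmp14 by at least 4.44-fold. This comparison crossed the 2 number formats, and 70 of 662 genes with several called probes (10.6%) had probes called in opposite directions. With median scaling 66.4% of called genes were higher, against 47.8%.

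In 5F against early 4F cells, which differ by a factor and possibly by passage, Ifitm3 rose by 5.50 ± 0.18 (SE), from 6.44 ± 0.10 to 11.94 ± 0.12 (SD, n = 2 each). Nkx2-2 was higher in 5F cells by at least 16.7-fold and Igf2bp3 by at least 12.8-fold. Ndn, a growth suppressor of neurons, was lower by 6.18, Efs by at least 24.4-fold and Stc2 by at least 35.5-fold. In all, 3391 genes differed, 1602 higher and 1789 lower in 5F cells, with 969 at least 2-fold, and no list passed. The 24 neural stem cell genes split into 6 that rose (8 adjusted over the list alone) and 6 that fell, with Fabp7 up by 2.17 and Sox21 down by 1.24. This comparison crossed the 2 number formats, 53 of 452 genes with several called probes (11.7%) had them in opposite directions, and 2070 genes were called without 5F replicate 2. With median scaling 62.7% of called genes were higher, against 47.2%.

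In 5F against late 4F cells, arrays of the same format, Acta2 was higher by at least 23.1-fold, at 10.15 ± 0.25 against 4.77 ± 0.22 (SD, n = 2 each). Nkx2-2 was higher by at least 15.5-fold and Ddit4l by at least 19.2-fold, while Efs was lower by at least 15.5-fold, Ndn by 4.64 and Stc2 by at least 22.9-fold. In all, 1357 genes differed, 724 higher and 633 lower in 5F cells, with 407 at least 2-fold. Arrays of the same format only gave 1715 genes (894 higher, 821 lower). Leaving out 1 array gave 693 genes without 5F replicate 1, 737 without 5F replicate 2, 698 without late 4F replicate 1 and 711 without late 4F replicate 2. With median scaling 41.3% of called genes were higher, against 53.4%.

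Of 17 p53 response and growth arrest genes 12 were higher in 5F than in late 4F cells (13 adjusted over the list alone) and 1 lower, with a median of 0.73 (adjusted p = 7.56e-07; adjusted p = 0.425 with an estimated correlation). Phlda3, an inhibitor of AKT signalling, was higher by 1.86 and Cdkn1c by at least 1.66-fold, while Gadd45a was lower by -1.53. Of 12 smooth muscle genes 3 rose, the same adjusted over the list alone (median 0.21, or 0 with bounds, mean 0.70, adjusted p = 0.0404; adjusted p = 0.425 with an estimated correlation), Acta2 and the calponin Cnn2 (1.20) most. Of 25 cell cycle genes 4 fell and 1 rose, also over the list alone (median -0.19, adjusted p = 0.0404; adjusted p = 0.574 with an estimated correlation), such as the mitotic genes Birc5 (-0.76) and Top2a (-0.71). The smooth muscle list did not pass with arrays of the same format only (adjusted p = 0.0514, camera). Leaving out either early 4F array gives that same fit. The list also did not pass without late 4F replicate 2 or 5F replicate 2 (means of 0.68). Its adjusted p over all alternatives ran from 0.00200 to 0.0755. The cell cycle list did not pass without late 4F replicate 2 (adjusted p = 0.0785) or 5F replicate 2 (0.156), with a range of 0.00549 to 0.156. Among 24 neural stem cell genes 6 rose (8 adjusted over the list alone) and 1 fell, with Ednrb up by 3.54 and the Notch target Hes5 by 1.17. The neural list did not pass (adjusted p = 0.0552; adjusted p = 0.701 with an estimated correlation), but passed in 6 other settings planned beforehand (0.0160 to 0.0346) and without late 4F replicate 1 (0.0328), with a range of 0.0160 to 0.107 over all alternatives.

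**Figure D4:**
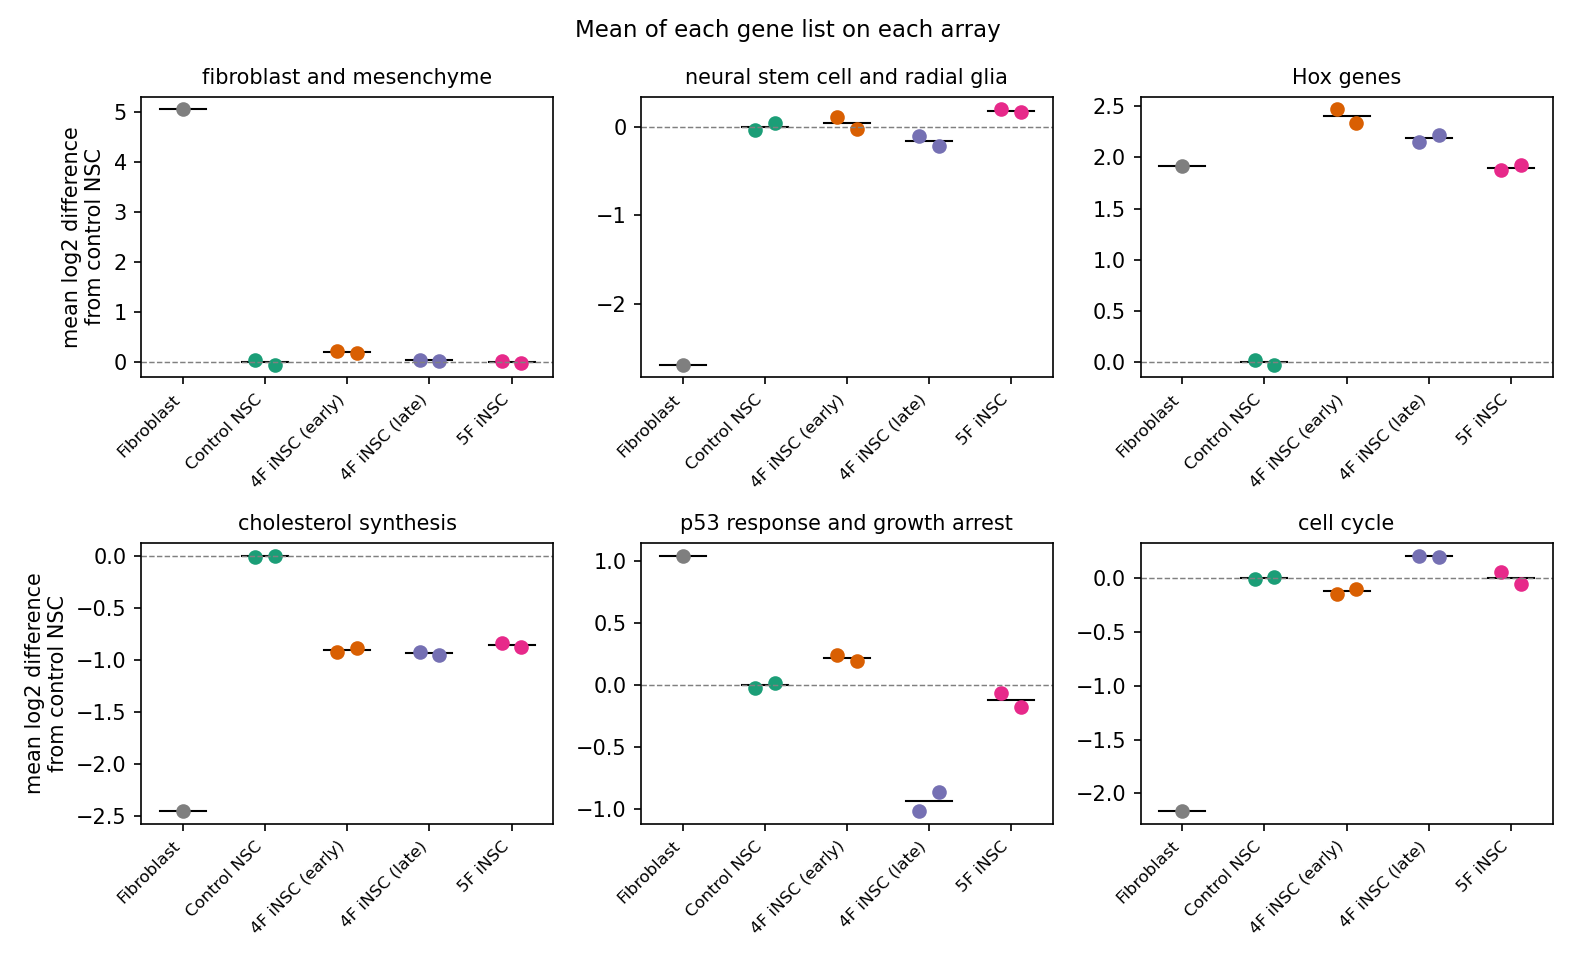
Mean log2 difference from control NSC (vertical) for 6 gene lists on each array, with points as arrays by group (horizontal) and lines as group means. The fibroblast list falls from fibroblast to the neural groups, while Hox genes stay higher and cholesterol synthesis genes lower in iNSC than in control NSC.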

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

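All tests of explanations in this part, with the second p53 list and the shuffled Hox profiles, were chosen only after the result was seen that they explain. For the number format on the Hox and p53 lists, opposite-going probes and fibroblast expression in early 4F cells, the values that decide the test were also known, and the condition on comparisons with fibroblast was added after its values were seen. The effects of the induced lines, each taken against the same control NSC, differed between lines in the tests listed here. Late and early 4F cells differed at 3885 genes, 5F and early 4F cells at 3391, and 5F and late 4F cells at 1357. The fitted difference of Pou3f4 from early 4F cells was -4.18 log2 in late 4F and -4.264 in 5F cells, and as these were below background it was lower by at least 11.9-fold and 12.3-fold. Sox2 was higher by 1.454 in late 4F and 1.624 in 5F cells than in early 4F cells on its brighter probe. The mean of the Sox2 probes pointed the other way without passing (-0.27 and -0.30). Klf4 was higher by 0.60 in 5F than in early 4F cells on its brightest probe, while its dimmer probes gave -0.29 and 0.16 without passing. The mean of the p53 list was -1.155 in late against early 4F cells and 0.814 in 5F against late 4F cells (adjusted p = 0.865 and adjusted p = 0.425 with an estimated correlation). The smooth muscle list had a mean of 0.703 and the cell cycle list -0.207 in 5F against late 4F cells (adjusted p = 0.425 and adjusted p = 0.574 with an estimated correlation). Neither passed with RMA-type background, the submitters' processed values, the mean of a gene's probes or without 5F replicate 2 or late 4F replicate 2. Of 26 genes named against control NSC, 18 differed between late and early 4F cells, 18 between 5F and early 4F cells, and 16 between 5F and late 4F cells. Over all genes 43.5%, 37.9% and 15.2% were called in these comparisons. The named genes were picked for large differences in 1 or more of the same lines, which favours differences between lines, so their counts decide nothing. Among 740 detected probes without a gene name, which the comparisons by gene do not use, 311 were called between early 4F cells and control NSC, 203 between late 4F cells and control NSC, and 158 between 5F cells and control NSC.

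Of 23 Hox genes, 12 were higher than in control NSC in all 3 iNSC groups and 1 was lower in each group; as a list they had adjusted p = 0.0788, adjusted p = 0.0570 and adjusted p = 0.0608 with an estimated correlation. Fibroblasts left in the cultures are argued against, for the 15 Hox genes called higher in fibroblast than in control NSC. Their signals would need a median fibroblast share of 82.1% in early 4F, 55.2% in late 4F and 46.6% in 5F cells. The lower quartiles were 43.4%, 30.6% and 18.3%. The 31 fibroblast genes gave a median share no higher than 0.012%. The number format is argued against, since 13 or more Hox genes were higher in late 4F and in 5F cells, whose arrays share the format of control NSC. A Hox pattern kept from the starting fibroblasts is a candidate explanation for part of this. Over 23 genes the shift from control NSC went with that of fibroblast, with Spearman rho of at least 0.624. For iNSC profiles shuffled over genes the median was 0.220 to 0.274 (permutation test, 100000 resamples, adjusted p at most 0.0185), although genes are not independent replicates. Hoxb4, Hoxb5, Hoxb6 and Hoxc6 lay between control NSC and fibroblast. A kept level does not account for genes above fibroblast. Hoxa2 had 6.19 in fibroblast and 8.68 to 9.19 on the iNSC arrays. In the same order Hoxa7 had 8.47 and 10.62 to 12.38, and Hoxd4 5.71 and 6.77 to 8.97. Hoxa5 had 10.38 and 11.62 to 12.57, and Hoxd8 7.89 and 9.39 to 9.64. Hoxa9, Hoxa10, Hoxd9 and Hoxb7 were above fibroblast on the 4F arrays but not on the 5F arrays. In fibroblast these had 5.19, 4.89, 5.99 and 9.55. On the 4F arrays they had at least 6.73, 5.88, 7.61 and 9.88. On the 5F arrays Hoxa9, Hoxa10 and Hoxd9 had at most 4.93, and Hoxb7 at most 9.03. The fibroblast array, the only one with Xist above background (8.99), need not match the cells the lines came from, and mouse stock, sex, the brain region behind the control NSC and an effect of the factors on Hox genes stay open, as untested.

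More genes were called between early 4F cells and the other neural groups than among those groups. Fibroblast expression left in early 4F cells stays open: 5 of 31 fibroblast genes were higher than in control NSC and 5 were lower, which decides nothing, while 262 of 780 fibroblast-high genes were still higher and 67 lower. The number format cannot be told apart from the group. Over 1826 genes called in early 4F against all 3 other neural groups, the fibroblast shift followed the early 4F shift with a slope of 0.629. Of these genes 71.4% to 71.7% went the same way. The bootstrap range, 0.543 to 0.702, resamples genes, which are not independent, and leaves out array error. Slopes were 0.358 to 0.367 for late 4F and 0.241 to 0.254 for 5F cells, over other genes, called against fewer groups. As part of the cause the format also stays open. At least 8.494% of genes with several called probes had them in opposite directions in the 3 comparisons of early 4F with the other neural groups. Within a format it was at most 2.98%. But comparisons with fibroblast across formats showed 1.65% to 2.28%, against 1.85% within. The early passage and the Pou3f4 signal stay open too, as untested.

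The p53 response list was lower in late 4F cells than in control NSC and in 5F cells. The number format is argued against, since these arrays share it and the list passed in both comparisons, the larger adjusted p being 8.27e-05 (adjusted p = 0.366 and adjusted p = 0.425 with an estimated correlation). Lower p53 activity is a candidate explanation: 23 measured genes of a second p53 list had medians of -0.384 against control NSC and -0.373 against 5F cells, and its camera test gave 0.0177 and 0.00305. With an estimated correlation these were 0.106 and 0.0601, and in each comparison 9 genes were lower, while 4 were higher than in control NSC (Cd82, 4.15, Casp1, 1.46, Dyrk3, 0.77, and Pltp, 0.59) and 3 higher than in 5F cells (Cd82, 2.17, Casp1, 1.53, and Tnfrsf10b, 0.96). A direct measure of p53, and a selection of cells over passages, were not available and stay open.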

How the results depend on the processing

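The fit to arrays of the same number format was the only one of the tests here chosen only after the result was seen. List values are mean log2 differences, positions are percents of the way from fibroblast to control NSC over fibroblast-high or NSC-high genes, and for every change listed the cause was not tested unless one is given.

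With RMA-type background the neural list in early 4F against control NSC was -0.0245 and the fibroblast list in 5F against control NSC -0.0570. In 5F against late 4F cells the smooth muscle list (0.96, adjusted p = 0.0559) and the cell cycle list (-0.21, adjusted p = 0.0559) no longer passed; over all alternatives these ran from 0.00200 to 0.0755 and from 0.00549 to 0.156. Positions were 91.2 and 87.3 for early 4F, 99.988 and 93.6 for late 4F, and 99.2 over fibroblast-high genes for 5F cells.

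Without background correction the Hox list in 5F against fibroblast was 0.0502, and the fibroblast list against control NSC was -0.0136 in late 4F and -0.0191 in 5F cells. The neural list in 5F against late 4F cells passed (0.33, adjusted p = 0.0160; range over alternatives 0.0160 to 0.107). Positions were 87.4 over NSC-high genes for early 4F, 100.4 and 89.8 for late 4F, and 99.4 and 94.2 for 5F cells. Of the 416 fibroblast-high and 292 NSC-high genes then left, 148 and 150 still differed in early 4F, 72 and 130 in late 4F, and 77 and 100 in 5F cells; the signatures otherwise held 780 and 685 genes.

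With an offset of 50 the Hox list in 5F against fibroblast was 0.0367, the neural list in 5F against late 4F cells passed (0.34, adjusted p = 0.0326), and the fibroblast list there was 0.00379. Positions were 96.7 over fibroblast-high genes for early 4F and 100.2 and 92.8 for late 4F cells.

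With median scaling Myc was -0.18 in early 4F against control NSC and -0.10 in 5F against late 4F cells. The Hox list in 5F against fibroblast was 0.0424, and the neural list was -0.20 in early 4F against control NSC, 0.0396 in late against early 4F, and 0.28 in 5F against late 4F cells (adjusted p = 0.0327). Positions were 96.9 and 77.9 for early 4F, 100.04 over fibroblast-high genes for late 4F, and 99.1 and 93.3 for 5F cells.

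With the submitters' processed values Myc in 5F against late 4F cells was -0.000221, the neural list in early 4F against control NSC -0.0213 and the fibroblast list in 5F against control NSC -0.0533. In 5F against late 4F cells the smooth muscle list (0.95) and the cell cycle list (-0.21) had an adjusted p = 0.0542. Positions were 91.3 and 87.1 for early 4F, 99.989 and 93.5 for late 4F, and 99.3 over fibroblast-high genes for 5F cells.

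Without a detection filter the fibroblast list in 5F against control NSC was -0.00198, and the neural list in 5F against late 4F cells passed (0.27, adjusted p = 0.0253). With detection on at least 2 arrays the Hox list in 5F against fibroblast was 0.12, the fibroblast list was -0.0763 in late 4F against control NSC and 0.16 in 5F against late 4F cells, and the neural list there passed (0.36, adjusted p = 0.0346). That filter drops genes detected in the lone fibroblast array alone, and positions over fibroblast-high genes were 79.6, 99.4 and 95.3 for early 4F, late 4F and 5F cells.

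With the mean of a gene's probes Sox2 was -0.27 in late and -0.30 in 5F against early 4F cells, 0.68 in early 4F against control NSC and -0.0307 in 5F against late 4F cells; its probes went opposite ways. Klf4 was 0.17 in early 4F against control NSC. In 5F against late 4F cells the fibroblast list was 0.0128, and the smooth muscle list (0.50) and the cell cycle list (-0.19) had an adjusted p = 0.0755. Positions were 96.1 and 87.2 for early 4F, 92.6 over NSC-high genes for late 4F and 96.0 for 5F cells. With a variance trend the neural list in 5F against late 4F cells passed (0.34, adjusted p = 0.0266). With arrays of the same format only, the smooth muscle list there did not (0.70, adjusted p = 0.0514).

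Leaving out 1 array moved these counts over 1.5 times. Late 4F against control NSC ran from 1444 to 2880 genes, with 1444 and 1495 without control NSC replicates 1 and 2, and 1583 and 1581 without late 4F replicates 1 and 2. For 5F against control NSC the range was 970 to 1934, with 970 and 1026 without the control NSC arrays and 1068 and 1097 without the 5F arrays. For 5F against late 4F it was 693 to 1715, with 693 and 737 without the 5F arrays and 698 and 711 without the late 4F arrays. For 5F against early 4F it was 2070 (without 5F replicate 2) to 3630.

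Among lists, leaving out 1 array gave these ranges in 5F against late 4F cells. Smooth muscle ran from 0.68 to 0.73, not passing without late 4F replicate 2, 5F replicate 2 or either early 4F array. Without an early 4F array the fit is the same as with arrays of the same format only. Cell cycle ran from -0.26 to -0.15, not passing without late 4F replicate 2 (adjusted p = 0.0785) or 5F replicate 2 (0.156). The neural list ran from 0.29 to 0.40, passing without late 4F replicate 1 (adjusted p = 0.0328). The fibroblast list against control NSC ran from -0.00789 (without control NSC replicate 2) to 0.0824 in late 4F cells. In 5F cells it ran from -0.0385 (without control NSC replicate 2) to 0.0517, with -0.00488 without 5F replicate 1. The neural list in early 4F against control NSC ran from -0.0267 (without early 4F replicate 1) to 0.11, and the Hox list in 5F against fibroblast from -0.0388 to 0.0112 (without 5F replicate 1).

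Among factors that did not pass, Klf4 against control NSC ran from -0.32 to 0.0654 (without control NSC replicate 2) in early 4F cells. In late 4F cells it ran from -0.0184 (without control NSC replicate 1) to 0.37, with -0.00881 without late 4F replicate 1. Myc ran from -0.17 (without early 4F replicate 1) to 0.19 in early 4F against control NSC, with -0.13 without control NSC replicate 2. In 5F against late 4F cells it ran from -0.12 (without 5F replicate 1) to 0.12, with -0.09 without late 4F replicate 1. Pou3f4, below background in these groups, ran from -0.32 to 0.15 (without 5F replicate 2) in 5F against late 4F cells and from -0.10 (without 5F replicate 1) to 0.37 against fibroblast. Positions over fibroblast-high and NSC-high genes ran from 95.1 to 96.0 and 86.7 to 88.3 for early 4F, 100.02 to 100.8 and 92.3 to 93.2 for late 4F, and 99.0 to 99.9 and 95.8 to 96.5 for 5F cells.

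With replicate number as a block the 10 comparisons gave 5116, 5103, 5291 and 5162 genes for control NSC, early 4F, late 4F and 5F cells against fibroblast, then 3778, 2330 and 1549 for early 4F, late 4F and 5F cells against control NSC. Late against early 4F gave 3788, 5F against early 4F 3224 and 5F against late 4F 1252. Differences between replicates 1 and 2 correlated across groups at -0.244 to 0.143, which gives no clear sign of a pairing by replicate number common to the groups. The lowest value, between late 4F and 5F cells, leaves a pairing across replicate numbers open, which the block does not take up. Outside leaving out arrays, 762 list values kept direction and side of the threshold, 17 reversed direction, 6 gained and 7 lost a call, and for values of named genes these were 3694, 8, 9 and 37. With 1 array left out they were 548, 5, 1 and 6 for lists and 2604, 9, 6 and 45 for named genes. Of the counts, 6 values moved, all of them without background correction, and 174 stayed, while with 1 array left out 13 moved and 115 stayed. Slide as a block was not run, since no slide was given. Signal over background limited dim genes: each group below background gives a fold only as a bound, and 39.3% to 41.0% of probes were detected per array.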

Other observations

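The genes in this part were chosen after their values were seen, save those named in the comparisons, and no tests here were chosen only after the result was seen. Thumpd1, a tRNA acetylation factor, had 9.60 log2 in fibroblast and 9.85 ± 0.03 (SD, n = 2) in control NSC, and was below background on all 6 iNSC arrays (at least 20.1-fold, 18.7-fold and 19.3-fold lower than in control NSC in early 4F, late 4F and 5F cells). Pdrg1, a prefoldin-like protein, had 9.96 and 9.90 ± 0.01 in the same groups and was likewise below background on all 6 iNSC arrays. Zic1, a neural and mesenchymal transcription factor, had 7.83 in fibroblast and 7.45 ± 0.23 in control NSC and was below background in the 3 iNSC groups. Whether mouse stock adds to such differences was not tested.

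Ttyh1, a chloride channel of neural stem cells, was at 6.41 ± 0.15 in control NSC and 11.28 ± 0.14, 10.19 ± 0.01 and 10.67 ± 0.01 in early 4F, late 4F and 5F cells (4.88, 3.78 and 4.26 higher). Ctsc, a lysosomal protease, had 10.42 ± 0.06 in control NSC and 5.84 ± 0.05 in 5F cells, and was below background in both 4F groups and in fibroblast. Twist1, a mesenchymal transcription factor, had 9.23 in fibroblast, was below background in control NSC, and had 7.71 ± 0.16, 8.37 ± 0.19 and 8.73 ± 0.06 in early 4F, late 4F and 5F cells. Pcolce, a collagen processing protein, had 11.15 in fibroblast, 5.24 ± 0.50 in control NSC and 7.64 to 7.93 in the iNSC groups.

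Late 4F cells stood apart at several genes. Ednrb, an endothelin receptor, had 8.40 ± 0.19 there, against 11.86 ± 0.04 in control NSC, 11.66 ± 0.24 in early 4F and 11.94 ± 0.03 in 5F cells. Gja1, a gap junction gene, had 7.12 ± 0.10 there, against 11.44 ± 0.01, 10.42 ± 0.08 and 10.81 ± 0.10. Cdkn1c, a cell cycle inhibitor, was below background in late 4F cells only. Cd82, a tetraspanin, had 9.89 ± 0.12 in late 4F cells, 7.72 ± 0.21 in 5F cells and 5.75 ± 0.03 in control NSC.

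S100b, a calcium-binding protein of astrocytes, had 6.64 ± 0.35 in control NSC and was below background in all 3 iNSC groups. Apoe, a lipid carrier, and Clu, a secreted chaperone, were below background in late 4F and 5F cells and detected in early 4F cells. Igfbp7, a secreted growth inhibitor, had 13.94 in fibroblast, 8.84 ± 0.06 in control NSC and 6.24 ± 0.07 in early 4F cells, and was below background in late 4F and 5F cells.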
